A study of Mus musculus with 6 samples.

How the data were processed

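Total RNA of tauGFP-positive cells, sorted from the dissected hindbrains of whole litters, was amplified, labelled with biotin and hybridized to Affymetrix Mouse Genome arrays, per the series design and the labels. The labels divide the 6 arrays into a control group and a swap group of 3 replicates each, and the series design calls the replicates independent and biological. The p-values therefore measure the spread between pooled litters of a genotype.

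The deposited table holds 1 linear intensity per probe set and array, for 45101 probe sets. The affy package was used, per the submitters' processing notes, and its version and the background and summary methods are not given in the sources used here. The deposited intensities have a 2% trimmed mean of 500 on every array, so the arrays had been scaled to a common mean. Their medians were 118, 130 and 139 in control arrays 1, 2 and 3 and 118, 122 and 139 in swap arrays 1, 2 and 3. The table has no detection calls, so no probe set could be called absent. The median SE of a log2 difference was 0.282 at or above the median level and 0.731 below it. Arrays correlated at r of 0.885 to 0.907 across probe sets, with no near-identical pair, and the first principal component (32.3% of the variance at or above the median level) set control array 1 and swap array 1 apart from the rest. Scanner files and hybridization dates were not used here, and no batch could be tested. The values were linear, as the fixed design allowed for, and log2 was taken with no offset because every intensity was above 0. Adding 64 to each intensity before log2 was tried as an alternative.

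Names came from the platform's probe table. Among the 45037 probe sets left after the 64 array control probe sets were taken out, 34945 had 1 gene symbol, 932 had several and 9160 had none, and no gene was named from the last 2 kinds. Of the Entrez identifiers 34741 matched the RefSeq gene table of the mouse assembly and 204 did not, and 0 symbols changed. No genome was used here, and the place of a probe set in its transcript is not known. A gene was represented by its probe set with the highest mean over the 6 arrays, a choice blind to genotype, which gave 18193 genes.

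Differences are swap minus control on the log2 scale, fitted per probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with two-sided p adjusted by the Benjamini-Hochberg method and a threshold of 0.05. Intervals are 95% intervals from the same fit. The 31 gene lists were fixed before the data were examined. They cover Hox genes and cofactors, hindbrain segmentation, motor neurons and their migration, signalling, progenitors and neurons, other cell types, and RNA quality. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. fry asks whether the genes of a list move, on balance, one way, or in its mixed form whether they change in either direction, and neither form compares the list with other genes. The adjusted p of these lists are over the 31 lists, and those of the 2 lists added later are over those 2. Single values were compared by an exact permutation test, whose smallest two-sided p is 0.1 with 3 against 3 arrays.

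The rule for naming genes was also set before the data were examined. It took Hoxb1 and a further gene that is not reported here, then the 10 largest changes per direction past the threshold with arrays that do not overlap, completed to 5 per direction by the smallest unadjusted p where fewer passed. For each list it took the members past the threshold or else up to 3 members with the smallest unadjusted p, and for lists of other cell types and of quality also the 3 members with the highest mean. Genes with clone or predicted names were not named. Members that did not pass are given as values.

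The scripts were tested on simulated data with the variances of the real probe sets, in which 200 probe sets were changed, 50 for each fold. With 22519 probe sets at or above the median level in the fit, 7, 35, 45 and 48 of 50 were recovered at 2-fold, 4-fold, 8-fold and 16-fold. In 20 simulated draws each, with genes drawn independently of one another, camera called the branchiomotor list in 0 draws without a shift and in 20 draws with a log2 shift of 0.5.

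Alternatives fixed beforehand were the replicate number as a block, a filter at the median level, quantile normalization, median centring, a prior that follows the level, array weights, other ways of joining probe sets, other thresholds, other list tests, and leaving out each array. Those added after seeing the data were the offset, leaving out both replicate 1 arrays, taking Otx2 out of its list, and 2 further gene lists.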

Results

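Gene expression was measured in mouse embryos at E10.5, in fluorescent cells sorted from hindbrains that had been pooled by litter. In both genotypes the reporter tauGFP, a green fluorescent protein fused to the microtubule-binding protein tau, was made from the Hoxb1 locus, so the sort took cells in which that locus was active. The labels give the tissue as rhombomere 4, the hindbrain segment that produces the facial branchiomotor neurons. The control group (n = 3 arrays) made the normal Hox-B1 protein. In the swap group (n = 3 arrays) the same locus made another Hox protein. Each array held an independent biological replicate, per the series design. The comparison asks whether the transcripts of these cells differ when another Hox protein stands in for Hox-B1. Array medians lay between 118 and 139 intensity units, and the number of arrays limits the precision of every value below.

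The sorted cells of both genotypes carried Isl1 and Tbx20, genes of the facial motor neuron list, at high intensities, and no gene passed the test between the genotypes. Isl1, a motor neuron transcription factor, stood at a log2 intensity of 13.71 ± 0.07 (SD, n = 3) in the control arrays and 13.84 ± 0.17 (SD, n = 3) in the swap arrays. Tbx20, a T-box factor of branchiomotor neurons, stood at 13.41 ± 0.12 and 13.60 ± 0.28 (SD, n = 3 each). Both genes were chosen after their values were seen. Of the gene lists fixed beforehand, camera called the forebrain and midbrain genes higher in the swap arrays, with a median log2 difference of 0.40 over 15 measured genes. This call was lost when camera estimated the correlation from the data (adjusted p = 0.983 in camera), and also with Otx2 taken out of the list.

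limma called 0 of 45037 probe sets at an adjusted p under 0.05, and the smallest adjusted p was 0.260. At an unadjusted p under 0.05 there were 2060 probe sets, 939 higher and 1121 lower in the swap arrays, against 2252 expected by chance. With a prior that follows the level and resists outlying variances, limma again called 0, with 1624 probe sets at an unadjusted p under 0.05. Of 18193 genes, 1610 (8.85%) had all 3 swap arrays on one side of all 3 control arrays, and chance gives 10%. The median log2 difference over all probe sets was -0.01.

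What the arrays could resolve depended on the level. Among the 22519 probe sets at or above the median level, an intensity of 114, the 95% interval of the difference lay within 2-fold for 61.3%, and below that level it did so for 3.96%. In data simulated for this comparison, all 45037 probe sets were first fitted. Of 50 changed probe sets per fold at or above the median level, limma recovered 0 at 2-fold and 11 at 4-fold. At 8-fold and 16-fold it recovered 32 and 43 of 50. With changed probe sets drawn from all levels, it recovered 0, 9, 13 and 18 of 50 at the same folds. Recovery was higher with only the 22519 probe sets at or above the median level in the fit. The changed probe sets from that level then gave 7, 35, 45 and 48 of 50. That fit of the real arrays also called 0 probe sets.

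**Figure D1:**
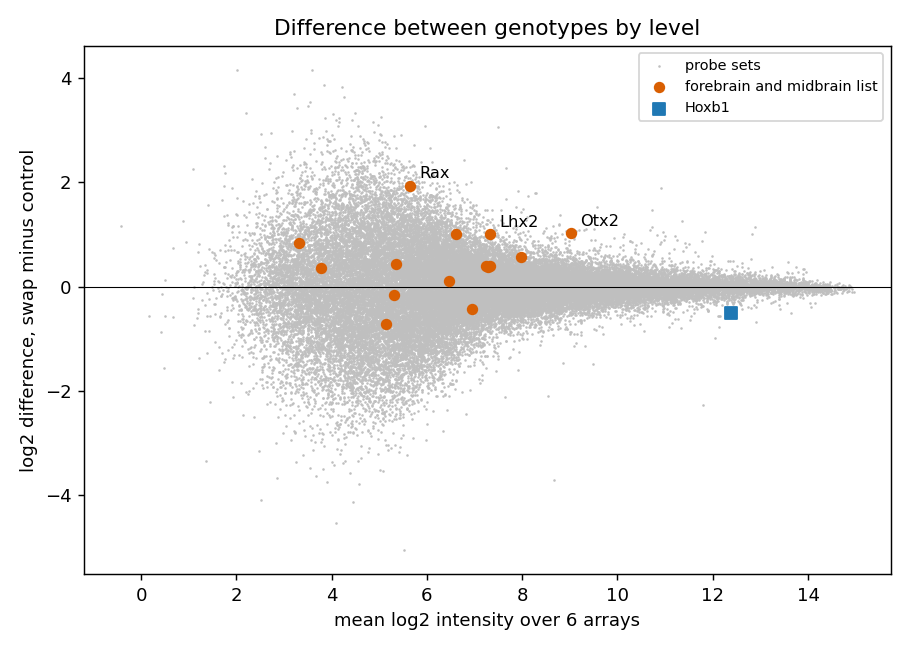
Log2 difference (swap minus control, vertical axis) against mean log2 intensity over the 6 arrays (horizontal axis) for each of the 45037 probe sets in grey, with the 15 measured forebrain and midbrain genes in orange and Hoxb1 in blue. The differences spread most at low levels, and 0 probe sets passed an adjusted p under 0.05 in limma (2060 had an unadjusted p under 0.05).

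Hoxb1 was measured by 1 probe set. Its log2 intensity was 12.63 ± 0.07 (SD, n = 3) in the control arrays and 12.13 ± 0.38 (SD, n = 3) in the swap arrays. The difference was -0.51 (SE 0.27, 95% interval -1.17 to 0.16), and limma's adjusted p was 1.00. All 3 swap arrays lay below all 3 control arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). The position of the probe set in the transcript is not known here, so its value does not check the labels.

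Of the 12 Hox genes of paralog groups 1 to 4, which pattern the hindbrain, 10 were measured, Hoxb1 among them, and 0 passed. The list's median difference was 0.19, with camera's adjusted p = 0.969. Hoxb3 stood at 11.25 ± 0.08 in the control arrays and 11.55 ± 0.26 in the swap arrays (SD, n = 3 each), a difference of 0.30 (0.16 without swap array 1), and Hoxd3 had a difference of 0.67 (SE 0.53, and 0.24 without control array 1). The TALE homeodomain proteins, which bind DNA together with Hox proteins, had 10 of 11 members measured and a median of 0.11 (adjusted p = 0.867). Meis1 was their member with the smallest p, at a difference of 0.40 (SE 0.23). The posterior Hox genes of groups 5 to 13 had 23 of 27 members measured, a median of -0.28 and an adjusted p of 0.707 in camera. fry's test for change in either direction, which does not compare the list with other genes, called these posterior genes (adjusted p = 0.00795), and 3 of the 23 lay at or above the median level. Their smallest p belonged to Hoxd10 (0.91), Hoxd11 (-1.03) and Hoxb9 (-1.58, and -0.89 without control array 1), all below the median level and none past limma's test.

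The branchiomotor neuron list, the genes by which facial motor neurons are recognised, had 21 of 22 members measured. Of these 11 were higher and 10 lower in the swap arrays, 0 passed, and the median was 0.06 (camera's adjusted p = 0.969). The 95% interval lay within 2-fold for 10 members. Isl1 differed by 0.13 (95% interval -0.40 to 0.66), Tbx20 by 0.19 (-0.41 to 0.79) and Ebf1 by 0.15 (-0.42 to 0.72), all 3 chosen after their values were seen, and without swap array 1 they were at 0.03, 0.03 and 0.07. Gfra1, a co-receptor for the growth factor GDNF, had the smallest p of the list and a difference of 0.53 (SE 0.21, limma's adjusted p = 1.00), but its other probe sets gave -0.94 and 0.31. Gata2 and Gata3, zinc-finger factors that act in hindbrain neurons, had differences of -0.79 (SE 0.46) and -0.42 (SE 0.25), with Gata2 at -0.30 without control array 1 and Gata3 at -0.26 without swap array 3. The cholinergic genes Chat, Slc18a3 and Slc5a7, chosen after their values were seen, stood below the median level, at 4.09, 4.99 and 3.61 in the control arrays.

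Genes of facial motor neuron migration and planar cell polarity were all measured (24), and 16 of them had a 95% interval within 2-fold. Their median was 0.07 and camera's adjusted p was 0.867. The smallest p belonged to Ptk7 (-1.13, SE 0.46, at a low level), the adhesion molecule Cntn2 (0.58, SE 0.26) and the kinase Cdk5 (0.63, SE 0.49), and without control array 1 Ptk7 was at -0.68 and Cdk5 at 0.18. Of the 32 axon guidance genes 0 passed, with a median of 0.10 (adjusted p = 0.470). The 8 somatic motor neuron genes had a median of -0.24 (adjusted p = 0.619), and the 9 measured serotonergic genes had a median of 0.07 (adjusted p = 0.969), with Tph2, the enzyme of neuronal serotonin synthesis, at 2.02 (SE 0.87) and a low level.

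The rhombomere segmentation list had 19 of 23 members measured, 14 higher and 5 lower in the swap arrays, and a median of 0.15. It did not pass (camera's adjusted p = 0.453). Its smallest p belonged to Otx2 (1.02), which is also in the forebrain and midbrain list, the FGF feedback inhibitor Spry4 (0.72, SE 0.29) and the growth factor Fgf3 (1.13, SE 0.64, and 0.43 without control array 1). The difference for Epha4, an Eph receptor known from rhombomeres 3 and 5 and chosen after its values were seen, was -0.05 (95% interval -0.57 to 0.47). The Eph receptor and ephrin list had 20 measured members and a median of -0.05 (adjusted p = 0.969), with Epha8 at -2.66 (SE 0.63, below the median level, limma's adjusted p = 0.815).

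The forebrain and midbrain list, fixed as a marker of brain regions outside the sort, was the 1 of 31 lists that camera called (adjusted p = 0.0340). Lhx2, Barhl2 and En1 were also in the hindbrain interneuron list, Otx2 and En1 in the segmentation list, and Lmx1a in the dorsoventral progenitor list. The forebrain and midbrain list therefore does not mark other regions alone. Of its 15 measured members 12 were higher and 3 lower in the swap arrays, and 3 had an unadjusted p under 0.05. With an estimated correlation camera's adjusted p was 0.983 (unadjusted 0.0362), and by fry it was 0.590 (unadjusted 0.0381). The list's estimated correlation was 0.019, near the preset 0.01, so correlation between its genes need not be what raised camera's p. In the segmentation list, with an estimated correlation of -0.041, camera's unadjusted p also rose, from 0.0438 to 0.0937. Otx2, a homeodomain factor of the forebrain and midbrain, stood at 8.51 ± 0.06 in the control arrays and 9.53 ± 0.30 in the swap arrays (SD, n = 3 each). Its difference was 1.02 (SE 0.24, 95% interval 0.42 to 1.62, limma's adjusted p = 0.818), and it was higher in 3 of 3 swap arrays. Lhx2, which also marks dorsal hindbrain interneurons, differed by 1.01 (SE 0.37), the eye-field factor Rax by 1.94 (SE 0.65, below the median level) and Barhl2 by 0.57 (SE 0.50, and 0.14 without swap array 1). The list's call was lost without control array 2 (median 0.79, adjusted p = 0.124), control array 3 (median 0.30, adjusted p = 0.364) or swap array 1 (median 0.36, adjusted p = 0.726), and with Otx2 taken out of the list, a test chosen after seeing the data (median 0.40, adjusted p = 0.262). camera called at least 1 list in 7 of the 9 other divisions of the 6 arrays into 3 and 3.

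**Figure D2:**
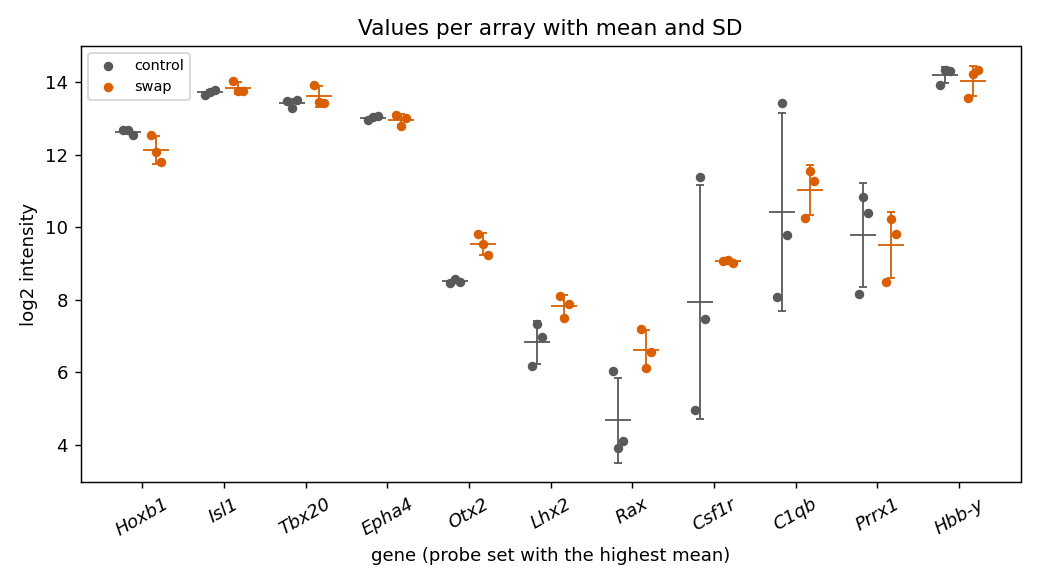
Log2 intensity (vertical axis) of single arrays for 11 genes, control in grey and swap in orange, with the mean and SD of the 3 arrays of each genotype. Isl1 and Tbx20 stood near 13.7 and 13.4 in the control arrays, Otx2 was higher in all 3 swap arrays, and the macrophage gene Csf1r ranged from 4.96 to 11.37 among the control arrays.

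Neuronal and progenitor programmes had 0 members past limma's test. Of 30 pan-neuronal genes 28 had a 95% interval within 2-fold, with a median of 0.08 (camera's adjusted p = 0.619), and Neurod4, a proneural factor, had a difference of 0.28 (SE 0.23, and 0.16 without swap array 1). Of 29 measured cell cycle genes 24 had such an interval, with a median of 0.05 (adjusted p = 0.552), and the mitotic checkpoint kinase Bub1b had a difference of 0.77 (SE 0.39). The neural progenitor list (21 measured) had a median of -0.02, with Zic1 at 0.46 (SE 0.28), and the Notch and proneural list (23 measured) had a median of 0.03, with Neurog1 at -0.52 (SE 0.26). Both had an adjusted p of 0.969. The dorsoventral progenitor list (21 measured) had a median of 0.05 and the hindbrain interneuron list (27 measured) a median of -0.07, again with an adjusted p of 0.969 each. Their smallest p belonged to Gsx2 (-1.15, SE 0.31) and Sox14 (1.31, SE 0.46), both at low levels.

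Among the signalling lists 0 members passed and camera called 0 lists, with 0 also by fry. The medians were -0.11 for retinoic acid signalling (16 measured, adjusted p = 0.969), 0.10 for Hedgehog signalling and the floor plate (15 measured, adjusted p = 0.619), -0.02 for FGF signalling (17 measured, adjusted p = 0.969) and -0.05 for Wnt targets (17 measured, adjusted p = 0.969). Gli1, a Hedgehog target, had a difference of 1.86 (SE 0.74) at a low level. The median, the mean and camera's direction differed in sign in 9 lists, those for Wnt targets, dorsoventral progenitors, interneurons, serotonergic neurons, neural progenitors, Notch, dissociation stress, branchial mesenchyme and sensory ganglia, whose smallest camera p was 0.621.

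Markers of macrophages and mesenchyme varied widely between arrays of the same genotype. Csf1r, a macrophage receptor, stood at 4.96, 11.37 and 7.48 in control arrays 1, 2 and 3 and at 9.07, 9.09 and 9.02 in the swap arrays. C1qb, another macrophage gene, stood at 8.08, 13.41 and 9.79 in the control arrays and at 10.26, 11.55 and 11.28 in the swap arrays. The mesenchymal factor Prrx1 stood at 8.16 in control array 1 and 8.48 in swap array 1, and between 9.83 and 10.82 in the other 4 arrays. The list medians were 0.41 for macrophages (14 measured, adjusted p = 0.619), -0.10 for branchial mesenchyme (23 measured, adjusted p = 0.969), 0.07 for neural crest and glia (15 measured, adjusted p = 0.969) and 0.06 for cranial sensory ganglia (14 measured, adjusted p = 0.969). They were 0.23 for otic and surface ectoderm (17 measured, adjusted p = 0.969) and 0.18 for endothelium (15 measured, adjusted p = 0.619). Tlx3, a factor of sensory ganglia and dorsal interneurons, had a difference of -0.97 (SE 0.37) below the median level.

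The erythroid list had 11 of 14 members measured, 10 of them lower in the swap arrays, and a median of -0.27. It did not pass (camera's adjusted p = 0.309, and adjusted p = 0.983 with an estimated correlation). The embryonic globin Hbb-y stood at 14.18 ± 0.22 and 14.03 ± 0.41 (SD, n = 3 each), with a difference of -0.15. Hba-a1 had the smallest p of the list, at a low level and a difference of -1.58 (SE 0.35, limma's adjusted p = 0.771).

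RNA and litter composition were followed with their own lists. The p53 target list (13 measured) had a median of 0.05, and the list of immediate early and dissociation stress genes (23 measured) had 12 members higher and 11 lower, each with an adjusted p of 0.969 in camera. Xist, which marks female cells, ranged from 11.33 to 12.74 in the control arrays and from 10.64 to 12.85 in the swap arrays. The sex list had a median of -0.24 (4 measured, adjusted p = 0.867 in camera). That list joins Xist with genes of male cells, so its median cannot show a shift in litter sex. Xist differed by -0.25, and the male genes Eif2s3y, Uty and Kdm5d by -0.28, -0.23 and -0.04. The log2 signal of the 3′ minus the 5′ control probe set for Actb was 2.55 ± 0.13 in the control and 2.63 ± 0.25 in the swap arrays (SD, n = 3 each, two-sided exact permutation p = 0.8), and for Gapdh it was 1.35 ± 0.07 in the control arrays (SD, n = 3) and 0.16 more in the swap arrays (exact permutation p = 0.8). Swap array 1 stood apart, at 2.92 for Actb and 1.93 for Gapdh.

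Of the 541 genes in the 31 lists 503 were measured. limma called 0 of them over all probe sets and 0 adjusted over the list alone, where the smallest adjusted p was 0.0512 in the erythroid list.

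**Figure D3:**
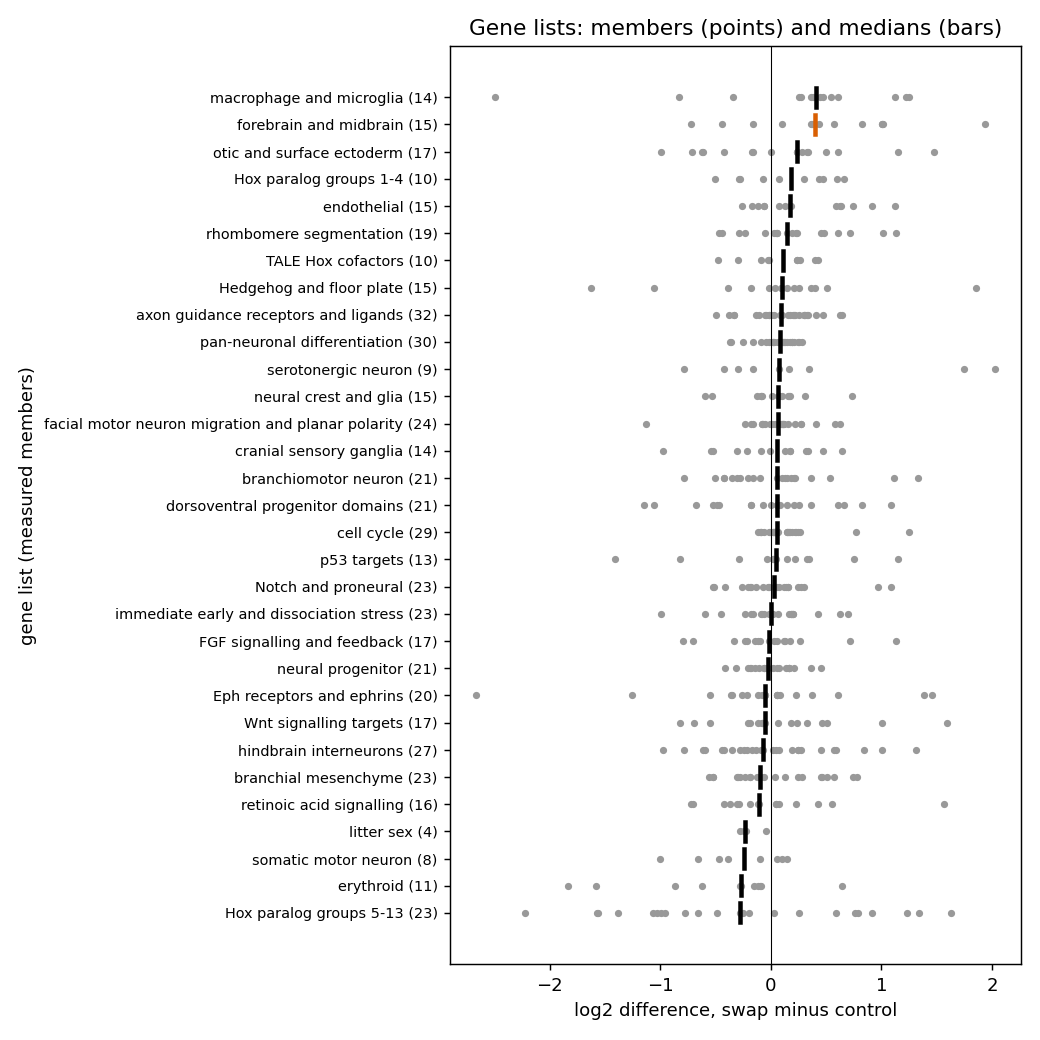
Log2 difference (swap minus control, horizontal axis) of each measured member (points) of the 31 gene lists (vertical axis, number of measured members in brackets), with the list median as a bar. The bar of the forebrain and midbrain list, the list that camera called, is orange and lies at 0.40.

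The genes with the smallest p in each direction all lay below the median level and did not pass limma's test. Those higher in the swap arrays were the mitochondrial carrier Slc25a18 (2.30, SE 0.26), Rfx8 (2.28, SE 0.28), the major urinary protein Mup5 (3.84, SE 0.49), Btbd18 (2.60, SE 0.35) and Fsip1 (2.71, SE 0.37). Those lower were Mlip (-2.65, SE 0.27), the muscarinic receptor Chrm3 (-2.59, SE 0.30), the sulfotransferase Sult1d1 (-3.48, SE 0.43), Trim75 (-2.17, SE 0.30) and the transporter Slc6a20a (-3.07, SE 0.45). Their adjusted p ranged from 0.268 to 0.408. The mean control intensity of Slc25a18 was 11.6 and its mean swap intensity 57.1, against a median level of 114. Of the 100 probe sets with the smallest p, 99 lay below the median level.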

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

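The offset, leaving out both replicate 1 arrays and taking Otx2 out of its list were chosen after the data were seen. The count of changed probe sets or genes was 0 in limma under all 18 alternatives run (smallest adjusted p 0.241). The 1.5-fold cut among them could only give 0, since the main fit called 0. At an unadjusted p under 0.05 there were 774 to 2375, where the 774 counts genes, with 1 probe set per gene. With the filter at the median level 838 had an unadjusted p under 0.05, over fewer probe sets. Hoxb1 kept its direction in every alternative that gave it a value, from -0.71 to -0.33 with 1 array left out. Its swap and control arrays do not overlap, so leaving out 1 array could not turn it. Of 676 values of 50 other genes of the naming rule or named in the comparison 664 kept direction and side, 0 became called, and the others turned in differences that had not passed. With 1 array left out, 21 of the 50 fell by over 1.5 times or turned.

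The number of called lists, 1 with all arrays, was 0 with median centring, the offset, both replicate 1 arrays out, the mean of a gene's probe sets, an estimated correlation, fry's one-way form, and Otx2 taken out. The forebrain and midbrain list's median difference in those settings was 0.43 (adjusted p = 0.0665), 0.25 (0.0791), 0.63 (0.112), 0.37 (0.0859), 0.40 (0.983), 0.40 (0.590) and 0.40 (0.262). The adjusted p of the list ran from 0.010 to 0.983 over all settings, and the cause was not tested. With 1 array left out, 0 to 2 lists were called and the median ran from 0.30 (without control array 3) to 0.79 (without control array 2). The cell cycle list was also called without control array 1 or swap array 3, the erythroid list without swap array 2, and without control array 2 the macrophage list alone was called.

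The replicate numbers were tried as a block. Same-numbered arrays deviated together with r of 0.0652, 0.0182 and 0.0573 over all probe sets and 0.234, 0.0313 and 0.224 at or above the median level (other pairs -0.287 to 0.123 there). Not every pair was over 0.1 at either level, so they were not taken as paired, though 5 of 6 arrays over all probe sets and 4 of 6 at or above the median level correlated best with their own number, a hint from the data and not the design. The replicate block left 0 calls in limma (2323 at an unadjusted p under 0.05). Each number occurs once per genotype, so the block cannot move a difference. Hoxb1 thus stayed at -0.51 and the median of the forebrain and midbrain list at 0.40. With the block camera's adjusted p of that list was 0.0197, and no other call changed.

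With 1 array left out, differences that had not passed turned for Csf1r (-0.36 to 2.84), C1qb (-0.57 to 2.10), Prrx1 (-1.10 to 0.24), Hbb-y (-0.29 to 0.088), Epha4 (-0.11 to 0.036) and Xist (-0.69 to 0.41). Without both replicate 1 arrays Isl1 was at -0.0052, Csf1r at -0.37 and C1qb at -0.18. Scaling moved the median of all probe sets by less than 0.1. Below the median level the median SE was 0.731, against 0.282 above it, which limits what low signals can show.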

Other observations

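The dorsal midline list, the 2nd forebrain and midbrain list with its division by level, the test of swap array 1, the test of other divisions for the count of probe sets, and the ranking under a prior that follows the level were chosen after results had been seen.

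A list of dorsal midline and choroid plexus genes was made after Otx2 and other dorsal genes had been seen in the swap arrays. The lists that share 4 of its genes had also been tested before. The dorsal midline list was higher in the swap arrays (20 of 22 genes measured, median log2 difference 0.31, camera's adjusted p over the 2 added lists = 0.00169). With an estimated correlation camera's unadjusted p was 0.0362 for the forebrain and midbrain list and 0.0219 for the dorsal midline list. Of the 16 members of the dorsal midline list at or above the median level 14 were higher, and without those 4 genes and Ttr its median was 0.32. The list kept an unadjusted p under 0.05 in the 16 alternatives run, with its median at 0.19 without control array 1 and at most 0.42. Ttr, the transthyretin gene that is abundant in choroid plexus, stood at 10.19, 13.78 and 12.98 in control arrays 1, 2 and 3 and at 13.12, 13.43 and 13.85 in the swap arrays, a difference of 1.15 (SE 0.94) with control array 1 far below the rest. The BMP decoy receptor Bambi differed by 0.87 (SE 0.29), the Wnt amplifier Rspo3 by 1.21 (SE 0.50), Bmp6 by 0.78 (SE 0.40), and the roof plate zinc-finger genes Zic5 and Zic1 by 0.57 (SE 0.27) and 0.46 (SE 0.28). Gdf10 (-1.17, SE 0.88) and Msx2 (-0.18, SE 0.34) went the other way, and none of these genes passed limma's test (adjusted p = 1.00 each). Without control array 1 Ttr was at 0.08, Bmp6 at 0.52, Gdf10 at -0.31 and Msx2 at 0.08.

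Under a prior that follows the level, which puts 47 rather than 99 of the 100 smallest p below the median level, the 10 leading genes at or above that level did not pass (smallest adjusted p = 0.356), and for some of them the probe sets of a gene differed. Glo1, the methylglyoxal-detoxifying glyoxalase, was lower in all 4 of its probe sets at that level, at -0.57, -0.43, -0.60 and -0.50. Ift27, a component of the intraflagellar transport of cilia, was higher in all 3, at 0.81, 0.83 and 0.69. Tmem18 (1.48) and Rbm45 (-2.28, with an SD of 0.83 in the swap arrays) had 1 such probe set each. Pan3 gave -0.99, -0.14 and -0.68, and Npr3 gave 1.10 and 0.53. The copper transporter gene Atp7a gave -1.47 and -0.14, Glce gave -1.61 and -0.07, Pde5a gave 0.88, 0.15 and 0.07, and 2 of the 6 probe sets of Trp53bp1 gave 1.79 and 1.83 (SD 0.74 and 0.72 in the control arrays) while the others lay between 0.09 and 0.20.

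The higher forebrain and midbrain list in the swap arrays was set against 3 explanations. For cells from other brain regions as its whole cause, a 2nd list of such genes showed no rise, but it does not settle the question. Its median was -0.30 over its 8 members at or above the median level, 0 of them higher. The upper 95% bootstrap bound, drawn over genes and not arrays, was -0.052, against a median of 0.40 in the first list. Each of the 8 had a 95% interval in limma that held 0. Without swap array 1 Sp8 (0.03), Lhx8 (0.21) and Tfap2d (0.09) were higher, and the others stayed lower. Of the 8, 4 stood above every member of the first list, where a small share of such cells would be hidden, and the other 4 were also lower, with a median of -0.34 and the same upper bound. A part played by such cells stays open, since of all 25 measured members 10 were higher, among them Vax1 (1.23, chosen after its values were seen), the 1 member with an unadjusted p under 0.05, below the median level (adjusted p = 0.754 in camera over the 2 added lists). More dorsal midline cells in the swap arrays stay open as an explanation. The dorsal midline list was higher by a median of 0.39 at or above the median level, with an upper bound of 0.78. It was made after dorsal genes had been seen in these arrays, so its rise is no independent support. The dorsoventral progenitor list fixed earlier did not pass (median 0.05, adjusted p = 0.969 in camera). That list holds genes of dorsal and ventral domains together, so its median cannot decide the question. Swap array 1, with the largest 3′ minus 5′ difference of the control probe sets, cannot be told apart as a source. Without it the forebrain and midbrain list's median was 0.36 (bootstrap 0.12 to 0.69, against 0.20, the all-array median divided by 2). A genotype effect on dorsal genes stays open and untested.

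The 6 arrays allow 10 divisions into 3 and 3, too few for a share under 0.05. For probe sets at an unadjusted p under 0.05, 7 of the 10 gave as many as the genotypes (real value 2060, highest other 3456, which set control array 1 and swap arrays 1 and 2 against the rest and points to a structure of the arrays other than genotype). For the forebrain and midbrain list 1 of the 10 gave a camera p as small (real value 0.0011, smallest other 0.0114), and for the dorsal midline list 1 of the 10 (real value 8.43e-04, smallest other 0.0949). In each case that 1 was the genotype division itself. Both lists were followed or made after its values were seen, so these ranks favour it and cannot decide the question. The smallest adjusted p in camera of any list fixed beforehand was 0.0340 in the genotype division and 2.75e-10 in another. camera called at least 1 such list in 7 of the 9 other divisions. Genes with 2 or more probe sets at or above the median level, all at an unadjusted p under 0.01 in one direction in limma, numbered 0 of 4767 for the genotypes, with 2060 single probe sets at an unadjusted p under 0.05. The highest count in the other divisions was 2. No division can give fewer than 0, so the divisions do not test this count. A planned test of neighbouring genes was not run because there was no such gene.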
